A study of Mus musculus with 28 samples.

How the data were processed

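Gene expression and T cell receptor libraries were made with the 10x Genomics 5′ kit from CD3-enriched cells, sequenced on a NovaSeq and counted with Cell Ranger 6.0.1, per the labels' protocols. Cells were merged and annotated with Seurat 4.0.5 in R 4.0.3 against mm10 (GRCm38), per the submitters' processing notes. The deposited table held natural log values, one per gene and cell, and the labels do not state the normalization step. Read back from the values, each was ln(1 + UMIs per 10000 of the cell), and 99.941% of the 65427391 values returned a whole count within 0.05 when scaled by the deposited UMI count of the cell. Recovered UMIs summed exactly to the deposited total in 88.7% of the 37260 cells (lowest ratio 0.984). The fixed plan had assumed whole counts, so the gene test was the one planned for normalized values.

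The table paired each of its 18388 rows with a gene ID and a symbol, which named the same gene in GENCODE vM21 (GRCm38) in 67.0% of rows (12322). In a block of rows the symbol lagged 1 row behind the ID, and in another the ID held for spleen cells only. Rows were therefore named by ID and symbol where both matched ahead of these blocks (11089 rows, 76.6% of UMIs), by the lagging symbol (1169 rows, 13.0%), by ID and symbol in plaque only in a later block (1042 rows, 0.736%) or by ID in spleen only (2344 rows, 3.33%). The remaining 2744 rows (6.34% of UMIs) were left out, 191 of them with a matching ID and symbol. As a check, the Cd79a row had UMIs in 99.5% of spleen B cells and 0.428% of other cells, the Foxp3 row in 95.5% and 3.17% of regulatory and other spleen cells, and the Gzmk row in 86.6% and 9.81% of plaque Gzmk effector memory and other cells. Mean levels in spleen and plaque correlated across rows by 0.855 in rows with agreeing names and -0.429 in rows known by ID only, which were not used in plaque. This left 14602 rows in spleen, 12421 in plaque and 11379 in both. Among genes named by the rule below, Ccr9, Cxcr5, Dapl1, Foxp3, Gzma, Ide, Klrb1c, Klre1, Myb, S1pr5, Sostdc1, Tsc22d3 and Zfp36l2 rest on the ID alone in spleen.

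Cell classes are the authors' deposited annotation. Some class names did not match their transcripts: the class named cardiomyocyte expressed collagen genes and the class named CD4 Complement expressed complement genes. CD8 and CD4 T cells were all cells of classes with these prefixes. For each library and cell set the mean normalized UMIs per 10000 over its cells was taken, with at least 20 cells per library, which left out aged replicate 3 and young replicate 1 from plaque CD4 T cells (19 and 9 cells). Genes with a mean of at least 0.1 in as many libraries as the smaller group were tested on log2(mean + 0.1) with limma 3.58.1 (trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Comparisons were aged against young within each tissue and cell set, the difference of these age effects between tissues, and plaque against spleen over both ages. Pearson's r of age effects across genes was computed once per cell set and given without a p-value. Values are per library, so that n counts libraries.

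Genes were named by a rule set, like the lists and comparisons, before the data were examined. Among called genes with at least 10 counts per library on average and no overlap between ages, the 10 largest rises and 10 largest falls were named (5 each way for the other contrasts, without the overlap condition for the difference of age effects), leaving out receptor segments, predicted and mitochondrial genes. Up to 4 called members of each list with the smallest p were added, as were Gzmk, Gzmb, Pdcd1, Tox, Eomes, Ccl5, Sell and Ccr7 in CD8 and Foxp3, Sell, Ccr7 and Pdcd1 in CD4 T cells. The text prints a selection. Coordinates are GRCm38 from GENCODE vM21. Gene lists covered naive and quiescence, cytotoxic effector, exhaustion and checkpoint, tissue residency, memory and migration, type I interferon, MHC class I, regulatory T, follicular helper, Th1, Th17, proliferation, immediate early, NF-kB and cytokine, cholesterol and lipid, ribosomal protein, mitochondrial, senescence, and markers of B and plasma, macrophage and natural killer cells. Lists of neutrophil, erythroid, platelet, smooth muscle and fibroblast, and endothelial markers had too few tested genes in T cells for a test, as did Th17 genes in spleen CD8 T cells. Lists were tested with camera (preset correlation 0.01) and fry on the limma values, in place of the edgeR counts first planned.

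Shares of cell classes were compared by two-sided exact permutation of libraries for classes with at least 10 cells, and by edgeR 4.0.16 on cell numbers. Shares of T cells in named clonotypes were averaged over 200 draws of 2782 T cells per library, and Trbv evenness over 200 draws of 895 (spleen) or 34 (plaque) CD8 T cells. Intervals of single-library shares are 95% Wilson intervals and cover counting error only. Other splits of the libraries were refitted, all of them within 1 tissue and 100 draws for contrasts of both tissues. For the difference of age effects the draws exchanged ages within each tissue, since an exchange across tissues turns the tissue difference into spread.

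The gene test was tested on simulated data with 100 genes changed 2-fold and 100 4-fold, of at least 10 counts per library on average. It recovered 93% and 98% of them in spleen CD8, 96% and 98% in spleen CD4, 54% and 85% in plaque CD8 and 17% and 81% in plaque CD4 T cells. For the difference of age effects it recovered 28% and 77% in CD8 and 7% and 49% in CD4 T cells, and unchanged genes made up at most 7.64% of calls. Alternatives tried were DESeq2 1.42.0, edgeR with and without TMM and low-count filter on recovered UMIs, pseudocounts of 0.01 and 1, no filter on low values, at least 50 cells per library, cells gated by their own Cd4 and Cd8 transcripts, a cell filter (over 5% mitochondrial UMIs or outside the 2.5 to 97.5 UMI percentiles, 1876 cells), no receptor segments, weights by cell number, TMM-scaled means, rows with agreeing names only, a length trend removed (lowess span 0.3), aged spleen replicates 1 and 2 averaged, fits without single libraries or cell classes, a joint model of all libraries, and the replicate number as a block. Analyses ran in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.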

Results

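Single cells from the spleen and from atherosclerotic plaque of young and aged female C57BL/6 mice were profiled after enrichment for CD3+ cells, so that most were T cells. Gene expression was measured in 14 libraries, 3 each from young and aged spleen and 4 each from young and aged plaque. Each had a T cell receptor library from the same cells. Spleen donors were 3 or 18 months old, and plaque donors were 5 or 21 months old. The plaque mice had received an adeno-associated virus that makes PCSK9, a protein that lowers the LDL receptor and so raises blood cholesterol, and then a Western diet for 10 weeks. Their aortic root and arch were digested to free the cells. The comparisons were of age in a lymphoid organ and in the diseased artery, and of the sites. The deposited table held 37260 cells with a class given by the authors, 18412 from young spleen, 11151 from aged spleen, 1999 from young plaque and 5698 from aged plaque.

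Library size ranged from 231 cells in young plaque replicate 1 to 6848 cells in young spleen replicate 1. The spleen libraries held 11856337 to 30934779 unique molecular identifiers (UMIs, counts of single transcripts) and the plaque libraries 2466470 to 27332285. The median depth per cell was 4079 ± 242 UMIs in young spleen and 3491 ± 488 in aged spleen (SD, n = 3 each). In plaque it was 7793 ± 1560 UMIs in young and 4368 ± 1585 in aged libraries (SD, n = 4 each), with 2000 in aged plaque replicate 1. The annotation held 13090 CD8 and 9777 CD4 T cells. The summed UMIs per library behind the gene comparisons were 4984752 to 13933246 for spleen CD8, 3232930 to 7846754 for spleen CD4, 218834 to 3415872 for plaque CD8 and 108895 to 589847 for plaque CD4 T cells.

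Naive classes took a smaller share and effector and follicular classes a larger share of T cells in the aged spleen. Naive CD8 T cells made up 34.0% ± 3.90 of T cells in young and 12.1% ± 6.05 in aged spleen, and naive CD4 T cells 21.4% ± 2.18 and 6.59% ± 2.17 (SD, n = 3 each). Gzmk effector memory CD8 T cells, named after a granule protease, were 0.507% ± 0.148 in young and 7.33% ± 2.03 in aged spleen. Follicular CD4 T cells, which help B cells, were 0.598% ± 0.322 and 11.9% ± 4.09, and Th1 CD4 T cells 0.143% ± 0.0748 and 1.97% ± 0.160. Regulatory CD4 T cells were 4.05% ± 1.48 in young and 8.95% ± 4.26 in aged spleen, without overlap between the ages. Double-negative T cells, which lack CD4 and CD8, showed the same order. Their naive class was 14.8% ± 1.12 in young and 5.44% ± 1.92 in aged spleen. Their Th1 class was 0.0575% ± 0.0101 and 2.43% ± 0.117, and the follicular class 0.155% ± 0.0835 and 3.10% ± 0.542. Lower in aged spleen were the classes with interferon-response genes, at 1.43% ± 0.112 in young and 0.306% ± 0.251 in aged spleen for CD8, and a gamma delta class, at 1.79% ± 0.190 and 0.574% ± 0.131. Central memory CD8 T cells were 7.28% ± 1.40 in young and 13.9% ± 5.05 in aged spleen, with overlapping libraries. Beyond T cells, B cells were 2.20% ± 0.181 of all cells in young and 3.68% ± 0.853 in aged spleen, and the macrophage class named M2 1.00% ± 0.411 and 2.42% ± 0.271.

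**Figure D1:**
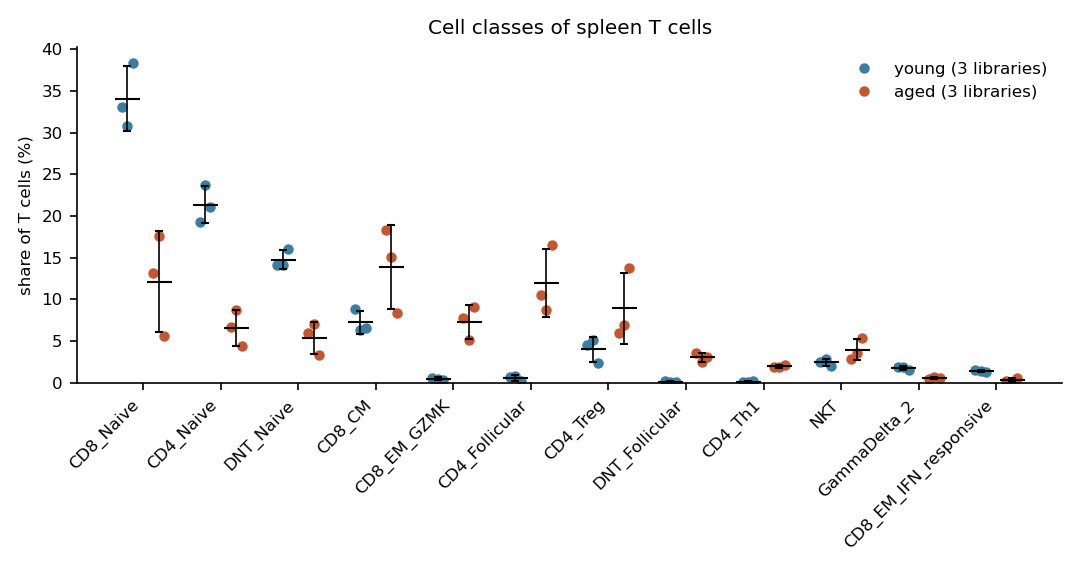
Share of T cells (%) in 12 T cell classes of the spleen, by age, with 1 point per library and the mean ± SD of 3 libraries per age. Naive classes lie lower and Gzmk effector memory, follicular and Th1 classes lie higher in all 3 aged libraries.

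Of 35 classes compared in spleen, 25 did not overlap between the ages, 18 higher and 7 lower in aged libraries, against 10% expected by chance. Each of these had a two-sided exact permutation p of 0.1, the smallest that 3 against 3 libraries allow, and an adjusted p of 0.14. The edgeR test on cell numbers called 24 classes, 17 of them higher. Shares of T cells sum to 100%, so a fall in 1 class raises the others, and the CD3 enrichment sets the share of cells other than T cells.

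CD8 T cells of the aged spleen carried more effector and memory transcripts and fewer naive transcripts as a whole, over all CD8 classes. Changes are given as differences of log2 mean normalized UMIs per 10000 with a pseudocount of 0.1, aged minus young, with their standard errors. This scale understates changes of low genes. S100a6 (ENSMUSG00000001025, chromosome 3, 90612882 to 90624181, GRCm38), a calcium-binding protein, rose from 0.544 ± 0.158 to 8.07 ± 1.62 normalized UMIs per 10000 (SD, n = 3 each), a log2 change of 3.67 ± 0.19 (limma adjusted p = 1.26e-05). Gzmk (ENSMUSG00000042385, chromosome 13, 113171608 to 113225908), a granzyme, rose from 0.0775 ± 0.0301 to 1.78 ± 1.43, a log2 change of 3.16 ± 0.41 (adjusted p = 0.00140). Ccl5 (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518), a chemokine that attracts leukocytes, rose from 14.2 ± 4.36 to 102 ± 24.6, by 2.86 ± 0.24 (adjusted p = 0.000113). Ccr7 (ENSMUSG00000037944, chromosome 11, 99144196 to 99155077), the receptor that guides T cells into lymphoid organs, fell from 4.72 ± 0.419 to 1.84 ± 0.232, a log2 change of -1.32 ± 0.12 (adjusted p = 0.000159). Lef1 (ENSMUSG00000027985, chromosome 3, 131110471 to 131224356), a transcription factor of naive T cells, changed by -1.14 ± 0.14 (adjusted p = 0.000928). In all 5 genes the 3 aged libraries lay beyond the 3 young ones. With every library weighted to equal shares of 5 CD8 classes, S100a6 kept 46.5% of its log2 difference, Gzmk 7.54%, Ccl5 11.7%, Ccr7 40% and Lef1 45%. Of the 949 called genes 58 turned to the other side.

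**Figure D2:**
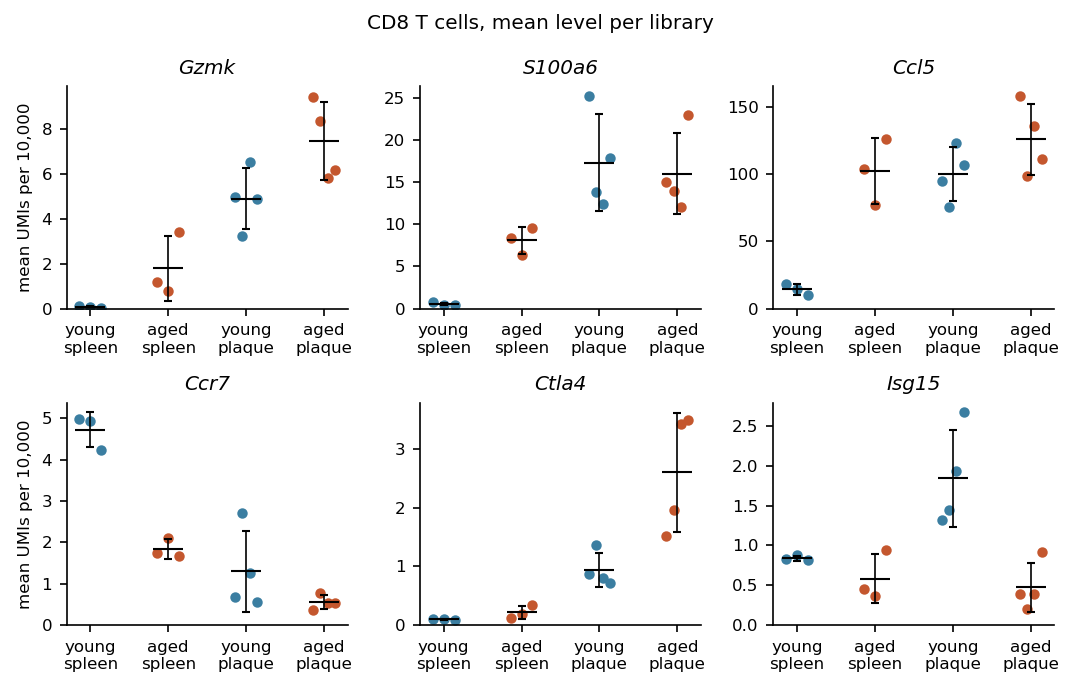
Mean normalized UMIs per 10000 per library of 6 genes in CD8 T cells of young and aged spleen and plaque, with 1 point per library and the mean ± SD of 3 (spleen) or 4 (plaque) libraries. Gzmk, S100a6 and Ccl5 lie higher and Ccr7 lower in all 3 aged spleen libraries, while in plaque Ctla4 lies higher and Isg15 lower with age.

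Other large rises in spleen CD8 T cells were Ccl4 (3.16 ± 0.51), a chemokine, Serpina3g (2.35 ± 0.27), a protease inhibitor, and Gzmm (2.27 ± 0.10), a granzyme. They were followed by Ccr5 (2.22 ± 0.26), a chemokine receptor, S100a4 (2.02 ± 0.22), Ctla2a (2.01 ± 0.19) and Xcl1 (1.96 ± 0.20), also a chemokine. Eomes, a transcription factor of memory and cytotoxic T cells, rose by 1.67 ± 0.23 (adjusted p = 0.00186). Large falls were Dynlt1b (-1.62 ± 0.12), whose near-identical copies leave its counts uncertain, Atp1b1 (-1.54 ± 0.10), Rgcc (-1.42 ± 0.10), Tsc22d3 (-1.39 ± 0.21), Ly6c1 (-1.28) and Ccr9 (-1.26 ± 0.13), a gut-homing receptor. Sell, the homing receptor L-selectin, fell by 0.55 ± 0.10 (adjusted p = 0.00961), a call lost without aged replicate 1 (adjusted p = 0.0619) or young replicate 2 (adjusted p = 0.0657). Gzmb, a granzyme, was 0.0373 in young and 0.290 ± 0.301 in aged spleen and did not pass (log2 change 1.25 ± 0.39, adjusted p = 0.0655). It passed without aged replicate 2 (adjusted p = 0.0401) or aged replicate 3 (0.000863).

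The fixed gene lists were compared with all other tested genes by camera at its preset correlation of 0.01, and 13 of 20 lists passed in spleen CD8 T cells, 11 higher and 2 lower. None of the 13 passed with a correlation estimated per list, and 7 passed in fry, which asks whether a list's own genes move on balance one way and compares them with no other genes. Where a list's count adjusted over the list alone is not given, it equalled the count over all tested genes. Of 14 genes of naive and quiescent T cells, 10 fell and 4 did not pass, among them Ccr7 and Lef1 (camera adjusted p = 5.05e-08, adjusted p = 0.234 with an estimated correlation). Adjusted over the list alone, 13 fell. Of 18 cytotoxic effector genes 14 rose, among them Klrk1 (1.73 ± 0.12), an activating receptor, and Id2 (1.33 ± 0.11), a regulator of effector fate. Adjusted over the list alone 15 rose (camera adjusted p = 3.42e-19, adjusted p = 0.233 with an estimated correlation). Of 15 memory and migration genes 13 rose, among them Ahnak (1.62 ± 0.11), Ccr2 (1.55 ± 0.13) and Itgb1 (1.17 ± 0.12), an integrin, which turned to the other side at equal class shares (-16.9% kept). This was 14 adjusted over the list alone (camera adjusted p = 2.52e-20, adjusted p = 0.233 with an estimated correlation). Of 6 exhaustion and checkpoint genes 4 rose, among them Ikzf2 (1.30 ± 0.21), a transcription factor, and 6 adjusted over the list alone (adjusted p = 4.25e-06, adjusted p = 0.264 with an estimated correlation). Of 8 tissue residency genes 5 rose, among them Runx3 (0.74 ± 0.11), and Itgae, the integrin CD103, fell (-0.87 ± 0.11). Adjusted over the list alone the counts were also 5 and 1 (adjusted p = 0.000661, adjusted p = 0.233 with an estimated correlation). Of 21 type I interferon response genes 9 fell, among them Ifi213 (-0.93 ± 0.12), and 14 adjusted over the list alone (adjusted p = 3.63e-05, adjusted p = 0.271 with an estimated correlation).

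Among the helper lists in spleen CD8 T cells, 5 of 6 Th1 genes rose, among them Il18rap (1.29 ± 0.14), a part of the interleukin 18 receptor (adjusted p = 3.62e-07, adjusted p = 0.233 with an estimated correlation). Of 6 follicular helper genes 3 rose, among them Maf (1.86 ± 0.20), and adjusted over the list alone 4 rose and 1 fell (adjusted p = 0.000308, adjusted p = 0.271 with an estimated correlation). Of 6 regulatory T genes 2 rose and 5 adjusted over the list alone (adjusted p = 9.08e-05, adjusted p = 0.271 with an estimated correlation). Natural killer genes rose in 4 of 5, among them Klre1 (1.72 ± 0.15), a killer cell receptor that memory CD8 T cells also carry (adjusted p = 5.4e-05, adjusted p = 0.234 with an estimated correlation). Of 12 mitochondrial genes 2 rose, among them mt-Nd3 (2.70 ± 0.18), and 3 adjusted over the list alone (adjusted p = 4.86e-05, adjusted p = 0.315 with an estimated correlation). Of 6 proliferation genes 1 rose, and adjusted over the list alone 2 rose and 1 fell (adjusted p = 0.0135, adjusted p = 0.494 with an estimated correlation). Of 14 MHC class I genes 3 rose, among them H2-Q6 (0.53 ± 0.09), and 4 adjusted over the list alone (adjusted p = 0.0464, adjusted p = 0.562 with an estimated correlation). That call was lost without aged replicate 3 (adjusted p = 0.291) or young replicate 3 (0.165).

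The other 7 lists did not pass in spleen CD8 T cells. Of 85 cytosolic ribosomal protein genes 2 rose and 7 fell (adjusted p = 0.0609), with 1 and 2 adjusted over the list alone. The list passed without aged replicate 3 (adjusted p = 1.48e-06) or young replicate 3 (0.000988). Of 14 immediate early genes, which tissue dissociation also induces, 1 rose and 2 fell (adjusted p = 0.114), or 1 and 4 adjusted over the list alone. The list passed without aged replicate 3 (adjusted p = 0.0441) or young replicate 1 (0.0171). Adjusted p was 0.803 for NF-kB and cytokine genes, with 2 falls among 11, 0.332 for 8 cholesterol and lipid genes with no single call (1 rise and 1 fall adjusted over the list alone), and 0.587 for 4 senescence genes with 1 fall. Markers of other cell types also moved with age in these cells. Among 4 B and plasma cell genes Igkc, an immunoglobulin light chain, rose (1.81 ± 0.35) and 1 gene fell, or 2 and 2 adjusted over the list alone (list adjusted p = 0.603). Of 3 macrophage genes 2 rose (list adjusted p = 0.0515), and this list passed without aged replicate 3 (adjusted p = 0.0411), young replicate 1 (adjusted p = 0.0261) or young replicate 2 (adjusted p = 0.0243).

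In all, 949 of 7576 genes changed with age in spleen CD8 T cells, 397 up and 552 down (limma, adjusted p under 0.05, two-sided). Ages did not overlap for 2508 genes (33.1% against 10% by chance), 945 of the called genes among them, and 2394 had an unadjusted p under 0.05. These p-values measure the spread between libraries, not between cells. The count was 351, 603 and 3080 without aged replicates 1 to 3, and 354 and 346 without young replicates 1 and 2. It was 484 with aged replicates 1 and 2 averaged to 1 sample. Count-based tests put more calls on the higher side, 958 of 1483 with DESeq2 and 904 of 1433 with edgeR and TMM scaling.

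In spleen CD4 T cells as a whole, over all CD4 classes, transcripts of follicular helper, regulatory and checkpoint genes rose with age while naive transcripts fell. Sostdc1 (ENSMUSG00000036169, chromosome 12, 36314139 to 36318452), a secreted antagonist of BMP and Wnt signals, rose from 0.0659 ± 0.00105 to 1.87 ± 0.536 normalized UMIs per 10000 (SD, n = 3 each), a log2 change of 3.53 ± 0.16 (limma adjusted p = 9.67e-08). Lag3 (ENSMUSG00000030124, chromosome 6, 124904361 to 124911705), an inhibitory receptor, rose from 0.0859 ± 0.0594 to 1.75 ± 0.649, by 3.30 ± 0.25 (adjusted p = 2.21e-06). Maf (ENSMUSG00000055435, chromosome 8, 115682942 to 115707794), a transcription factor of follicular helper cells, rose from 0.424 ± 0.0731 to 3.49 ± 0.326, by 2.78 ± 0.12 (adjusted p = 6.81e-08). Ccr7 fell from 5.44 ± 0.531 to 1.60 ± 0.0385 (log2 change -1.70 ± 0.10, adjusted p = 4.29e-07) and Sell from 3.45 ± 0.222 to 0.995 ± 0.304 (-1.74 ± 0.17, adjusted p = 1.55e-05). Pdcd1, which encodes the inhibitory receptor PD-1, rose from 0.231 ± 0.0587 to 1.16 ± 0.469 (1.89 ± 0.21, adjusted p = 3.53e-05). At equal shares of 7 CD4 classes (not Th1, interferon-response and Complement) the log2 difference kept within them was 16.7% for Sostdc1. It was 41.9% for Lag3, 33.5% for Maf, 35.4% for Ccr7, 30.0% for Sell and 15.3% for Foxp3. Pdcd1 turned to the other side (-10.4%), as did 168 of 2217 called genes.

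Further rises in spleen CD4 T cells were Ccl5 (3.09 ± 0.26), S100a6 (2.79 ± 0.17), Tigit (2.57 ± 0.16), an inhibitory receptor, and Gzmk (2.47 ± 0.19). Further falls were Ly6c1 (-2.33 ± 0.21), Dapl1 (-2.27), Pdlim4 (-2.22), Tsc22d3 (-1.71) and Lef1 (-1.61 ± 0.12). Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245), the regulatory T cell factor, rose from 0.964 ± 0.272 to 1.74 ± 0.596 (0.78 ± 0.22, adjusted p = 0.0188), a call lost without young replicate 3 (adjusted p = 0.0575). Of 20 lists 16 passed camera, 13 higher and 3 lower. None of the 16 passed with an estimated correlation, and 15 lists passed fry. Of 10 follicular helper genes all 10 rose, among them Il21 (2.41 ± 0.15), a cytokine for B cells, and Tox2 (2.18 ± 0.15). All 10 also passed adjusted over the list alone (adjusted p = 1.01e-11, 0.185 with an estimated correlation). Of 11 regulatory T genes 10 rose, among them Itgb8 (1.81 ± 0.11) and Izumo1r (1.66 ± 0.15), and 10 adjusted over the list alone (adjusted p = 9.39e-08, adjusted p = 0.253 with an estimated correlation). Of 7 exhaustion genes all 7 rose, among them Ikzf2 (2.38 ± 0.17) and Tox (1.23 ± 0.13), with 7 adjusted over the list alone (adjusted p = 6.66e-08, adjusted p = 0.185 with an estimated correlation). Of 13 naive genes 12 fell, and 12 adjusted over the list alone (adjusted p = 1.01e-11, 0.185 with an estimated correlation).

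Memory genes rose in 13 of 15 in spleen CD4 T cells, among them Ahnak (1.86 ± 0.10), Itgb1 (1.46 ± 0.11) and Cd44 (1.34 ± 0.10). At equal class shares Itgb1 (-3.26% kept), Nkg7 (-5.83%) and Ifng (-31.4%) turned to the other side and Cxcr3 kept 14.4%. The count was also 13 adjusted over the list alone (adjusted p = 5.23e-11, adjusted p = 0.185 with an estimated correlation). Of 14 cytotoxic genes 10 rose and 1 fell, among the rises Nkg7 (2.03 ± 0.13), with 10 and 2 adjusted over the list alone (adjusted p = 9.19e-06, adjusted p = 0.185 with an estimated correlation). Of 7 Th1 genes 6 rose, among them Ifng (1.15 ± 0.11) and Cxcr3 (1.91 ± 0.24), and 7 adjusted over the list alone (adjusted p = 2.12e-05, adjusted p = 0.185 with an estimated correlation). All 3 Th17 genes rose (adjusted p = 0.00592, 0.253 with an estimated correlation). So did 6 of 10 residency genes, among them Bhlhe40 (2.45 ± 0.18), also 6 adjusted over the list alone (adjusted p = 0.000209, adjusted p = 0.185 with an estimated correlation). Of 12 NF-kB and cytokine genes 8 rose, among them Tnfsf8 (2.19 ± 0.14) (adjusted p = 0.000209, adjusted p = 0.313 with an estimated correlation). Of 14 MHC class I genes 4 rose, among them H2-Q6 (1.16 ± 0.10) (adjusted p = 0.0056, adjusted p = 0.466 with an estimated correlation). Mitochondrial genes rose in 9 of 12, among them mt-Nd3 (2.88 ± 0.15), and in 10 adjusted over the list alone (adjusted p = 0.000209, adjusted p = 0.268 with an estimated correlation). Type I interferon genes fell in 10 of 21, among them Usp18 (-1.23 ± 0.16) and Ifi214 (-1.13 ± 0.12), and in 11 adjusted over the list alone (adjusted p = 0.000201, adjusted p = 0.313 with an estimated correlation). Of 84 ribosomal protein genes 25 fell, among them Rplp0 (-0.98 ± 0.12), and 2 rose, or 3 adjusted over the list alone. The list was lower (adjusted p = 0.000254, adjusted p = 0.563 with an estimated correlation), a call lost without aged replicate 3 (adjusted p = 0.200).

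Markers of other cell types rose with these groups in spleen CD4 T cells. All 6 B and plasma cell genes rose, among them Igkc (2.46 ± 0.14) and Cd74 (2.29 ± 0.24), a part of antigen presentation (adjusted p = 5.51e-05, adjusted p = 0.185 with an estimated correlation). Of 9 macrophage genes 5 rose, or 7 adjusted over the list alone (adjusted p = 0.0056, 0.466 with an estimated correlation). Fcer1g (0.95) and Tyrobp (0.78) were at 0.09 and 0.19 within the 7 classes set equal above, so other classes carried most of both rises. The lists of proliferation (1 rise and 1 fall, adjusted p = 0.462), immediate early (4 and 3, 0.742), cholesterol and lipid (3 and 2, 0.55) and senescence genes (2 and 2, 0.86) did not pass. Adjusted over the list alone, each of the first 3 had 1 more fall. The median (-0.01) and mean (0.20) of the senescence list differ in sign. In all, 2217 of 8047 genes changed, 1358 up and 859 down (limma). This takes aged replicates 1 and 2, perhaps of 1 animal, as 2 samples. Ages did not overlap for 3362 genes (41.8% against 10% by chance), and 3122 had an unadjusted p under 0.05. TMM-scaled means turned the split to 1146 up and 1668 down.

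In plaque, 2 of 28 classes did not overlap between the ages, against 2.86% by chance. T cells with both CD4 and CD8 were 1.67% ± 1.04 of T cells in young and 0.310% ± 0.368 in aged plaque (SD, n = 4 each). Cells without a class were 0.428% ± 0.123 of all cells in young and 4.69% ± 4.32 in aged plaque. Each had an exact permutation p of 0.0286, the smallest possible, and an adjusted p of 0.267. Gzmk effector memory CD8 T cells were 21.8% ± 6.44 of T cells in young and 32.5% ± 6.80 in aged plaque (exact p = 0.0571). The larger gamma delta class was 40.2% ± 12.3 and 28.4% ± 9.42 (exact p = 0.143). Smooth muscle cells were 10.5% ± 6.03 of all cells in young and 4.96% ± 1.76 in aged plaque (exact p = 0.0571), and M1 macrophages 25.6% ± 13.5 and 23.7% ± 13.5 (exact p = 0.771). No class passed the adjustment in plaque, and the edgeR test on cell numbers called 0 classes.

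In aged plaque CD8 T cells Tigit and Ctla4 were higher and Isg15 lower, calls lost without young replicate 3. Tigit (ENSMUSG00000071552, chromosome 16, 43648867 to 43664146), an inhibitory receptor, rose from 1.60 ± 0.389 to 4.08 ± 1.02 normalized UMIs per 10000 (SD, n = 4 each), a log2 change of 1.30 ± 0.20 (limma adjusted p = 0.0135). Ctla4 (ENSMUSG00000026011, chromosome 1, 60887000 to 60915832), another inhibitory receptor, rose from 0.944 ± 0.291 to 2.61 ± 1.02, by 1.33 ± 0.24 (adjusted p = 0.0274). Ier3 (ENSMUSG00000003541, chromosome 17, 35821684 to 35822923), an immediate early gene, rose from 0.241 ± 0.130 to 0.938 ± 0.281, by 1.66 ± 0.27 (adjusted p = 0.0135). Isg15 (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818), a ubiquitin-like protein induced by interferon, fell from 1.84 ± 0.614 to 0.475 ± 0.305, a log2 change of -1.84 ± 0.29 (adjusted p = 0.0135). Hbb-bs, a hemoglobin chain and so a marker of red cells, was 0.107 ± 0.0486 in young and 2.36 ± 3.12 in aged plaque (2.86 ± 0.49, adjusted p = 0.0201), with its highest level, 7.03, in aged replicate 4. The other named rises were Rgs16, a brake on G protein signals, from 0.790 ± 0.320 to 2.62 ± 1.46 (1.54 ± 0.27, adjusted p = 0.0237), Tent5c (1.03 ± 0.19, adjusted p = 0.0274) and Bhlhe40, a transcription factor (0.91 ± 0.17, adjusted p = 0.0355).

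Several genes central to the spleen comparison did not pass in plaque CD8 T cells. Gzmk was 4.89 ± 1.34 in young and 7.43 ± 1.74 in aged plaque (0.61 ± 0.20, adjusted p = 0.527), and Ccl5 99.9 ± 20.2 and 126 ± 26.5 (0.33 ± 0.17, adjusted p = 0.808). Pdcd1 was 2.81 ± 0.598 and 5.20 ± 3.28 (0.70 ± 0.28, adjusted p = 0.657). Gzmb was 3.08 ± 2.22 and 2.71 ± 1.34 (-0.02 ± 0.39, adjusted p = 0.998). Eomes was 1.19 ± 0.528 and 2.51 ± 0.482 (1.11 ± 0.26, adjusted p = 0.151) and passed without young replicate 1 (adjusted p = 0.0136). Adjusted p was 0.875 for Tox, 0.981 for Sell and 0.638 for Ccr7. In all, 9 of 7200 genes changed, 8 up and 1 down (limma), 458 had an unadjusted p under 0.05, and ages did not overlap for 292 genes (4.06% against 2.86% by chance). No gene passed without the filter on low values (700 at an unadjusted p under 0.05), and 2 passed in cells gated by their own Cd4 and Cd8 transcripts. Without young replicate 3 no gene passed either (432 at an unadjusted p under 0.05). The adjusted p was then 0.0810 for Tigit, 0.0810 for Ier3, 0.0862 for Isg15, 0.201 for Ctla4, 0.126 for Hbb-bs, 0.126 for Rgs16, 0.0965 for Tent5c and 0.254 for Bhlhe40. Without young replicate 1 the count was 29 and without young replicate 2 it was 4. Other single libraries also ended calls. Without aged replicate 3 the adjusted p was 0.0568 for Ier3, 0.108 for Ctla4, 0.0940 for Tent5c and 0.0967 for Bhlhe40. Without aged replicate 4 it was 0.0754 for Ctla4, 0.0875 for Tent5c and 0.0867 for Bhlhe40, and without aged replicate 2 it was 0.121 for Bhlhe40. Without young replicate 2 it was 0.0599 for Hbb-bs, 0.147 for Rgs16, 0.147 for Tent5c and 0.166 for Bhlhe40. Without young replicate 4 it was 0.0841 for Rgs16, 0.113 for Ctla4, 0.0841 for Tent5c and 0.0796 for Bhlhe40.

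Camera called 9 of 20 lists in plaque CD8 T cells, 5 higher and 4 lower, of which none passed with an estimated correlation and none in fry. Type I interferon genes were lower as a group, with 1 of 20 called and 15 falling when adjusted over the list alone (adjusted p = 2.15e-19, adjusted p = 0.11 with an estimated correlation). Exhaustion genes were higher, with 2 of 12 called and 5 adjusted over the list alone (adjusted p = 1.1e-07, adjusted p = 0.163 with an estimated correlation). Regulatory T genes were also higher, with 1 of 7 called and 2 adjusted over the list alone (adjusted p = 8.81e-06, adjusted p = 0.11 with an estimated correlation). Naive genes were lower, with 0 of 11 called, and 1 rise and 6 falls adjusted over the list alone (adjusted p = 3.41e-05, adjusted p = 0.267 with an estimated correlation). The calls of 5 further lists rested on single libraries, and 1 of their genes, Bhlhe40, was called. Residency had 2 rises and 1 fall adjusted over the list alone, memory 1 fall and immediate early 1 rise. Proliferation genes were lower (adjusted p = 0.000657, adjusted p = 0.439 with an estimated correlation), but not without aged replicate 3 (adjusted p = 0.306) or young replicate 4 (adjusted p = 0.0525). Immediate early genes were higher (adjusted p = 0.00138, adjusted p = 0.326 with an estimated correlation), but not without aged replicate 3 (adjusted p = 0.306). Residency genes were higher (adjusted p = 0.0245, adjusted p = 0.214 with an estimated correlation), but not without any 1 library other than young replicate 4. The adjusted p was 0.224, 0.199, 0.233 and 0.475 without aged replicates 1 to 4, and 0.117, 0.0553 and 0.135 without young replicates 1 to 3. Memory genes were lower (adjusted p = 0.042, adjusted p = 0.499 with an estimated correlation), but not without aged replicate 2 (0.0669) or 3 (0.407) or young replicate 1 (0.0923) or 4 (0.397). Mitochondrial genes were higher (adjusted p = 0.0449, adjusted p = 0.5 with an estimated correlation), but not without aged replicate 1 (0.139), 2 (0.0669) or 3 (0.164) or young replicate 3 (0.0552) or 4 (0.871).

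Of the 11 lists that did not pass in plaque CD8 T cells, adjusted p was 0.155 for cytotoxic, 0.694 for MHC class I, 0.131 for follicular helper, 0.188 for Th1, 0.156 for Th17 and 0.133 for NF-kB genes. It was 0.235 for cholesterol, 0.0822 for ribosomal protein, 0.229 for senescence, 0.81 for B and plasma cell and 0.545 for macrophage genes, the last with a median log2 change of 0.20. None of their genes was called over all tested genes. Adjusted over the list alone, cytotoxic genes had 2 rises and 1 fall, NF-kB, senescence and B cell genes 1 rise and 1 fall each, and follicular helper genes 1 rise. Cytotoxic genes passed without aged replicate 3 (adjusted p = 0.000967) and macrophage genes without aged replicate 3 (0.0187) or young replicate 4 (0.0246). Follicular helper genes passed without aged replicate 1 (0.00412) or 4 (0.0480) or young replicate 1 (0.00424), 2 (0.0163) or 4 (0.0289), with a median of -0.02 in all libraries. Th17 genes passed without aged replicate 2 (0.0106) or young replicate 1 (0.0113), and ribosomal protein genes, as higher, without aged replicate 1 (0.00168) or 2 (0.00117) or young replicate 1 (0.00203) or 2 (0.00637).

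CD4 T cells of aged plaque carried more transcripts of macrophage genes than those of young plaque. Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), a lipid carrier that macrophages secrete, rose from 0.355 ± 0.475 to 8.34 ± 5.94 normalized UMIs per 10000 (SD, n = 3 each), a log2 change of 4.59 ± 0.54 (limma adjusted p = 2.9e-05). C1qa (ENSMUSG00000036887, chromosome 4, 136895917 to 136898803), a complement chain made by macrophages, was 0.0541 ± 0.0937 in young and 2.75 ± 1.06 in aged plaque (adjusted p = 1.64e-05). The size of its change depends on the pseudocount because young cells held almost no UMIs. Lyz2, which encodes lysozyme, rose from 0.330 ± 0.252 to 5.54 ± 3.69 (3.67 ± 0.43) and Ccl4 from 1.26 ± 1.14 to 12.7 ± 9.14 (3.41 ± 0.49, adjusted p = 0.000357). Gzmb was the 1 gene that fell, from 1.75 ± 1.16 to 0.240 ± 0.184 (-2.36 ± 0.52, adjusted p = 0.0345), and Lag3 rose from 0.116 ± 0.202 to 1.07 ± 0.481 (2.76 ± 0.55, adjusted p = 0.0151). Single libraries ended both calls. Gzmb was lost without aged replicate 1 (adjusted p = 0.139), aged replicate 2 (0.217), young replicate 3 (0.416) or young replicate 4 (0.297). Lag3 was lost without aged replicate 1 (0.0718), 2 (0.206) or 4 (0.0856) or young replicate 2 (0.127) or 3 (0.133).

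Macrophage genes as a list were higher in plaque CD4 T cells, with 7 of 10 called and all 10 adjusted over the list alone (camera adjusted p = 5e-41, adjusted p = 0.00623 with an estimated correlation). B and plasma cell genes were higher, with 3 of 5 called and 4 adjusted over the list alone (adjusted p = 4.71e-12, adjusted p = 0.0326 with an estimated correlation). Among them was Cd74 (2.57 ± 0.43), which macrophages also express and whose call was lost without young replicate 3 (adjusted p = 0.0643). Exhaustion genes were higher, with 1 of 8 called and 6 adjusted over the list alone (adjusted p = 6.83e-09, adjusted p = 0.032 with an estimated correlation). Regulatory T genes were higher with no single call and 4 adjusted over the list alone (adjusted p = 0.000277, adjusted p = 0.467 with an estimated correlation), but not without young replicate 2 (0.0587). Of the other 5 lists called, 1 gene passed over all tested genes, Atf3 (adjusted p = 0.0231). It was lost without aged replicate 1 (0.249), 2 (0.164) or 4 (0.0891) or young replicate 2 (0.0598) or 3 (0.161). Immediate early genes had 2 rises adjusted over the list alone, follicular helper genes 2 and mitochondrial genes 1. Immediate early genes were higher (adjusted p = 0.00113, adjusted p = 0.467 with an estimated correlation), but not without aged replicate 1 (0.159) or young replicate 4 (0.154). Follicular helper genes were higher (adjusted p = 0.0141, adjusted p = 0.402 with an estimated correlation), but not without aged replicate 2 (adjusted p = 0.1995). Type I interferon genes were lower (adjusted p = 0.00136, adjusted p = 0.467 with an estimated correlation), but not without aged replicate 2 (0.249) or young replicate 4 (0.125). Ribosomal protein genes were lower (adjusted p = 0.00113, adjusted p = 0.689 with an estimated correlation), but not without aged replicate 2 (0.345) or young replicate 2 (0.329). Mitochondrial genes were higher (adjusted p = 0.0448, adjusted p = 0.689 with an estimated correlation), but not without aged replicate 1 (0.151) or 2 (0.345) or young replicate 3 (0.0836) or 4 (0.552).

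Of the 11 lists that did not pass in plaque CD4 T cells, adjusted p was 0.844 for naive, 0.826 for cytotoxic, 0.624 for residency, 0.111 for memory, 0.705 for MHC class I, and 0.0592 for Th1 genes. It was 0.176 for Th17, 0.893 for proliferation, 0.0696 for NF-kB, 0.705 for cholesterol and 0.89 for senescence genes. Cytotoxic genes had 2 rises and 1 fall, or 2 and 3 adjusted over the list alone, where memory and Th1 genes had 1 fall each and Th17 genes 1 rise. The naive list had a median of -0.03, a mean of 0.10 and a test direction upward, so these differ in sign. The naive list passed as higher without young replicate 2 (adjusted p = 0.00125), and the cytotoxic list without aged replicate 2 (0.00562). Memory genes passed as lower without aged replicate 4 (0.0356) or young replicate 2 (0.00174), and Th1 genes as lower without aged replicate 1 (0.00253) or young replicate 2 (0.000465). Th17 genes passed without aged replicate 2 (0.0115), and NF-kB genes without aged replicate 1 (0.00109) or young replicate 4 (0.00771).

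In all, 27 of 7212 genes changed in plaque CD4 T cells, 26 up and 1 down (limma, 3 against 3 libraries), 415 had an unadjusted p under 0.05, and ages did not overlap for 751 genes (10.4% against 10% by chance). The count was 16 without aged replicate 4, 17 without aged replicate 2 and 17 without young replicate 3. It was 9 without the filter on low values, 6 with a pseudocount of 0.01 and 2 in cells gated by their own Cd4 and Cd8 transcripts. Without both aged replicates 1 and 4 only aged replicate 2 stayed in the aged group, so no count is given for that setting. Without the few cells of a class named CD4 Complement, which carry macrophage transcripts, 6 genes passed, among them Ccl4 (3.30) and Lag3 (2.78). Apoe (1.75, adjusted p = 0.772), C1qa (adjusted p = 0.228) and Lyz2 (0.79, adjusted p = 0.981) did not. Sell, Ccr7 and Pdcd1 (adjusted p = 0.973, 0.84 and 0.944) did not pass in plaque CD4 T cells.

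The difference between the age effects of plaque and spleen was tested directly. In CD8 T cells S100a6 was 17.3 ± 5.73 in young and 16.0 ± 4.83 in aged plaque (SD, n = 4 each). Its age effect was lower in plaque than in spleen by a log2 difference of -3.77 ± 0.33 (limma adjusted p = 2.12e-06). Ccl5 differed by -2.53 ± 0.30 (adjusted p = 0.000205), S100a4 by -2.19 ± 0.35 (adjusted p = 0.00522), and Ahnak by -1.80 ± 0.25 (adjusted p = 0.00123). Itgb1 (ENSMUSG00000025809, chromosome 8, 128685654 to 128733200), an integrin, differed by -1.71 ± 0.26 (adjusted p = 0.00254) and Id2 by -1.54 ± 0.24 (adjusted p = 0.00310). Gzmk differed by -2.55 ± 0.46 (adjusted p = 0.0137), a call lost without young spleen replicate 3 (adjusted p = 0.0566). In CD4 T cells, Itgb1 rose with age in spleen from 1.55 ± 0.226 to 4.41 ± 0.286. In plaque it was 7.77 ± 1.58 in young and 4.41 ± 0.586 in aged cells (difference -2.25 ± 0.25, adjusted p = 0.00149). Ahnak differed by -2.14 ± 0.26 (adjusted p = 0.00227) and S100a6 by -2.49 ± 0.34 (adjusted p = 0.00518), the latter lost without young plaque replicate 3 (adjusted p = 0.0502). Class shares were not set equal in this test. In spleen CD8 T cells at equal class shares, S100a6 kept 46.5% of its age difference, Id2 34.8%, Ahnak 21.3% and S100a4 14.7%. Ccl5 kept 11.7%, Gzmk 7.54% and Itgb1 -16.9%. In spleen CD4 T cells S100a6 kept 42.7%, Ahnak 33.8% and Itgb1 -3.26%. Naive CD8 T cells were 1.06% to 3.32% of T cells in young plaque, so a shift between spleen classes stays open as a cause.

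In all, the age effect differed for 23 of 8016 genes in CD8 T cells, 2 higher (Tent5c and Cytip) and 21 lower in plaque (limma, 694 at an unadjusted p under 0.05). It differed for 14 of 8261 genes in CD4 T cells, 6 higher and 8 lower (837 at an unadjusted p under 0.05). The CD8 count was 10 and 15 without aged spleen replicates 1 and 3, and 12, 11 and 11 without young spleen replicates 1 to 3. The CD4 count was 30, 9 and 5 without aged plaque replicates 1, 2 and 4, and 124, 2 and 26 without young plaque replicates 2, 3 and 4. It was 3, 3 and 6 without aged spleen replicates 1 to 3, and 3 without any 1 young spleen library. With libraries weighted by cell number 5 genes passed in CD8 and 0 in CD4 T cells (234 at an unadjusted p under 0.05). With ages exchanged within each tissue, 5 of 100 splits reached the CD8 count and 8 of 100 the CD4 count. In CD8 T cells Tigit, Bhlhe40 and Ier3, 3 genes in all, rose in both tissues, against 0.263 expected from independent lists of 353 and 5 genes. In CD4 T cells 15 did, against 3.01 expected from 1138 and 18. The class named CD4 Complement held 6 plaque cells, all aged, and 79 cells in aged spleen replicate 3, against 7 to 12 in the other spleen libraries. Without it the macrophage list in plaque CD4 T cells had a median log2 difference of 0.949 in place of 3.27. Cells with macrophage transcripts in both tissues thus stay open as a cause of the CD4 overlap. Pearson's r between the age effects of both tissues was 0.161 across genes in CD8 and 0.214 in CD4 T cells, and genes are not independent replicates.

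Plaque T cells were also compared with spleen T cells over both ages. In CD8 T cells the heat shock genes Hspa1a (ENSMUSG00000091971, chromosome 17, 34969190 to 34972156) and Hspa1b were higher in plaque by log2 differences of 7.79 ± 0.19 (limma adjusted p = 8.18e-17) and 7.65 ± 0.27. They are near-identical copies whose reads cannot be separated with certainty. Hspa1a was at 0.0802 normalized UMIs per 10000 in young spleen, 0.0279 in aged spleen, 29.1 in young plaque and 35.2 in aged plaque. Nr4a1 (ENSMUSG00000023034, chromosome 15, 101254269 to 101274795), an early gene of receptor signalling and of dissociation, was higher by 5.65 ± 0.20. Also higher were Pdcd1 at 4.19 ± 0.26, Gzmb at 3.62 ± 0.34, Gzmk at 3.51 ± 0.23 (adjusted p = 1.93e-10), Ccl5 at 1.57 ± 0.15 and Tox at 1.53 ± 0.17. Sell was lower by -2.70 ± 0.30 (adjusted p = 6.02e-07), Ccr7 by -1.82 ± 0.23 and Igfbp4 by -2.94 ± 0.30. In CD4 T cells Hspa1a (7.76 ± 0.28, adjusted p = 2.33e-11), Bhlhe40 (4.44 ± 0.22), Ifng (4.33 ± 0.21), Cxcr6 (3.84 ± 0.29), a receptor of resident cells, and Pdcd1 (2.53 ± 0.30) were higher. Sell (-2.78 ± 0.51) and Ccr7 (-2.17 ± 0.29) were lower. In all, 2807 genes differed in CD8 T cells, 1450 up and 1357 down, and 1975 in CD4 T cells, 685 up and 1290 down, or 1303 without aged spleen replicate 1. With DESeq2 the CD4 split turned to 1634 up and 951 down. Tissue was confounded with batch (1 for plaque, 1 for spleen), digestion, diet, viral vector and donor age, so these cannot be told apart. Class shares differed too (naive CD8 34.0% of T cells in young spleen, 1.86% in young plaque). Markers of macrophages (Lyz2 1.83 ± 0.29, Apoe 2.32 ± 0.52) were also higher in plaque CD8 T cells. Of the B and plasma cell genes, Ighm (-1.60) and Cd79b (-1.13) were lower and Igkc (1.57) and Cd74 (1.80) higher.

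Clonotypes named by the authors took a larger share of T cells in aged than in young spleen. The deposited annotation named 36 clonotypes with at least 6 cells each, 744 cells in all, and named none in plaque cells, so plaque expansion was not analysed. The 6 cells were counted over the libraries together, and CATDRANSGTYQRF reached them with 2 cells in aged replicate 1 and 4 in aged replicate 2. Names thus rest on size in these same cells, and smaller clones of either age were not seen or compared. At 2782 T cells per library, clonotypes with at least 2 cells covered 1.54% ± 0.372 of T cells in young and 4.26% ± 1.65 in aged spleen (SD, n = 3 each). The difference was 2.72 points (exact permutation p = 0.1, the smallest possible), or 1.77 without aged replicate 3. Aged libraries were at 3.24%, 3.38% and 6.16% and young libraries at 1.82%, 1.68% and 1.12%. One name was the invariant alpha chain of natural killer T cells, with 399 cells, 328 of them in the natural killer T class. Without that chain the shares were 0.181% ± 0.193 and 2.78% ± 0.409 (difference 2.60 points, exact permutation p = 0.1). Aged replicates 1 and 2 shared 17 of their 19 and 18 other clonotypes, while no other pair of libraries shared more than 4.

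**Figure D3:**
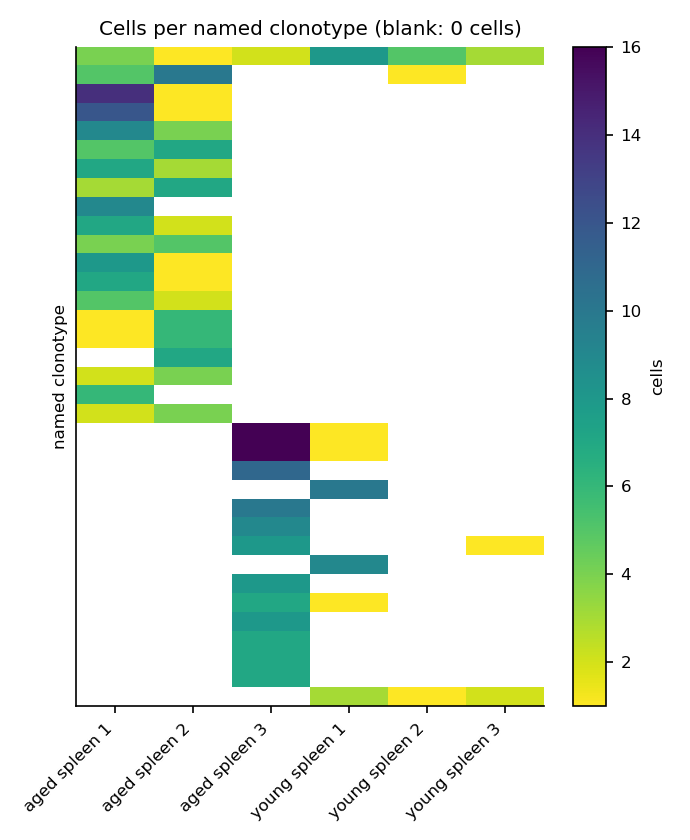
Cells of 35 named clonotypes (rows) in the 6 spleen libraries (columns), with blank fields for 0 cells and the natural killer T chain left out. Aged replicates 1 and 2 share 17 clonotypes, and most clonotypes have no cell in the young libraries. Clonotypes under 6 cells over the libraries together were not named or shown.

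Use of the T cell receptor beta variable (Trbv) genes in CD8 T cells was read from their transcripts. In spleen, evenness as the inverse Simpson index at 895 cells per library was 16.3 ± 0.292 in young and 15.8 ± 0.491 in aged libraries, from 24 genes (SD, n = 3 each, difference -0.484, exact permutation p = 0.3). The difference was -0.204 without aged replicate 3. In plaque, at 34 cells per library and 14 genes, it was 6.90 ± 2.25 in young and 5.98 ± 2.62 in aged libraries (SD, n = 4 each, difference -0.926, exact permutation p = 0.629). Without aged replicate 4 it was 0.347 higher in aged plaque. In that library 407 of 601 CD8 T cells with a call used Trbv3, 67.7% (95% Wilson interval 63.9 to 71.3%, counting error only). The most used gene took 14.8% to 41.2% in the other plaque libraries and 8.78% to 10.8% in spleen. Fewer Trbv genes could be read in plaque (14) than in spleen (24), which can raise shares there, so the tissues cannot be compared by them. A Trbv3 UMI was found in 58.0% of its 719 CD8 T cells (interval 54.4 to 61.6%, median depth 3912 UMIs). This compared with 10.8% of its M1 macrophages (8.79 to 13.2%, median 11643) and 3.29% of its gamma delta cells of class 1 (1.93 to 5.55%, median 4510), which should lack it.

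**Figure D4:**
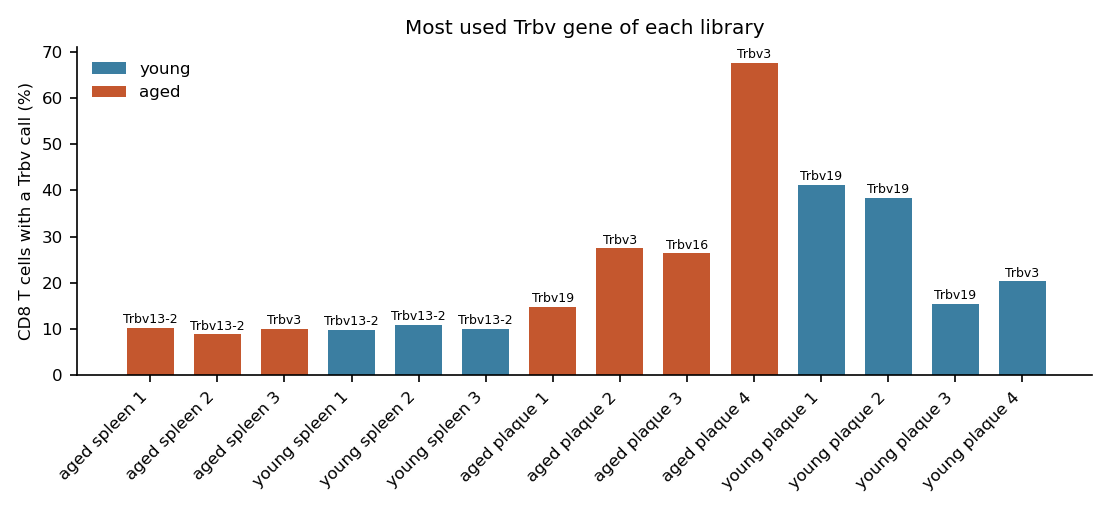
Share of the most used Trbv gene (% of CD8 T cells with a Trbv call) in each of the 14 libraries, coloured by age, with the gene's name above its bar. Spleen libraries sit between 8.78% and 10.8%, and aged plaque replicate 4 reaches 67.7% with Trbv3.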

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

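All tests of explanations below were chosen after the results were seen. Of 88 series of 4 plaque values tested for a value far from the others, chance marks about 1 in 20, and groups of 3 were not tested.

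The difference of the age effect between plaque and spleen passed for 23 genes in CD8 and 14 genes in CD4 T cells. In CD8 T cells the named differences were S100a6 (-3.77), Gzmk (-2.55), Ccl5 (-2.53), S100a4 (-2.19) and Xcl1 (-2.08), with a lower age effect in plaque, and Tent5c (1.25) and Cytip (0.89), with a higher one. With the ages exchanged within each tissue, 5 of 100 splits gave at least 23 genes, the highest other 51, so chance was not excluded. In CD4 T cells they were S100a6 (-2.49), Maf (-2.30), Itgb1 (-2.25), S100a4 (-2.19) and Ahnak (-2.14) on the lower side and C1qc (2.91), Ccl6 (2.5), Mafb (2.19), Tent5a (2.01) and Selenop (1.83) on the higher side, where the values of C1qc and Mafb depend on the pseudocount because young plaque held almost none of their UMIs. For CD4 T cells 8 of 100 such splits gave at least 14 genes, the highest other 229, so chance was not excluded. A count that high points to a structure of the samples, and all but 1 of these other splits in both cell sets kept the ages of the spleen libraries apart. When labels were exchanged across tissues as well, the highest count was 1600, from a split that set all plaque against all spleen libraries. Of these genes only S100a6, S100a4 and Ccl5 in CD8 and Itgb1 and Ahnak in CD4 T cells passed without each library in turn. At equal class shares the spleen age difference kept was 46.5% for S100a6, 14.7% for S100a4 and 11.7% for Ccl5 in CD8 T cells. It was -3.26% for Itgb1 and 33.8% for Ahnak in CD4 T cells, so a shift between spleen classes stays open.

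Aged spleen replicates 1 and 2 shared 17 clonotypes, where none of the other 14 pairs of spleen libraries shared more than 4. Crossing of barcodes or reads was argued against by 12 shared cell barcodes, fewer than the 17.9 expected from other pairs. Chains that arise in many mice were argued against by the same 17, since such chains would also link aged replicate 3, which shared 1 with either. A candidate explanation that stays open is that both libraries hold cells of 1 animal or of 1 pooled suspension, as their CD8 profiles differed by a chi-square of 1.80 per degree of freedom, against 3.29 for the next most alike pair of a group and 1.17 to 1.18 for random parts of 1 library. Age as the cause was argued against by the same counts, since it would link aged replicate 3 as well. With both libraries averaged to 1 sample, 484 genes passed in spleen CD8 T cells in place of 949.

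Macrophage genes were higher in aged than young plaque CD4 T cells, by a median of 3.27 on the log2 scale. Free RNA of macrophages was argued against as the whole cause, since the same list had a median of 0.378 (SD 0.778) in CD8 T cells of the same libraries. A few cells with macrophage transcripts in the class may account for most of it, as the median was 0.949 (SD 0.534) without the 6 cells of the class named CD4 Complement, all in aged plaque. The labels record no removal of doublets and none was done here, so doublets or cells bound to T cells stay open, as does an effect of age, which was not tested.

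In naive CD8 T cells of the aged spleen, transcripts under 600 nt were higher against those of 1000 to 4000 nt by a log2 gap of 0.340, although over all genes the age difference rose slightly with length (rank correlation 0.0794, and 0.107 without ribosomal protein genes). A change in ribosomal protein genes as a group was argued against as the whole cause, since the gap was 0.325 (bootstrap SE 0.0191) without these genes. An effect of the libraries on transcripts by length stays open, as the gap was also 0.312 in B cells, 0.331 in central memory CD8 T cells and 0.168 in regulatory T cells. The lower depth of the aged libraries could also account for it, as the gap fell with median UMIs per cell over the 6 spleen libraries (Pearson's r -0.873, exact permutation p = 0.00694, Spearman's rho -0.886, p = 0.0333), with r at -0.786 without the 2 libraries farthest from the median depth. Depth went with age in these libraries, so age itself, which was not tested, stays open.

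Other single libraries lay far from the rest of their group. Naive CD8 T cells were 3.65% of T cells in aged plaque replicate 3 (7 of 192 cells, 95% Wilson interval 1.78 to 7.33%), against 1.10% to 1.30% in the other aged plaque libraries. Double-negative regulatory T cells were 5.73% there (11 cells, interval 3.23 to 9.97%), against 1.52% to 1.97%. Double-negative naive T cells were 0.948% in young plaque replicate 2, from 2 of 211 T cells (interval 0.260 to 3.39%), and 0 in the other young plaque libraries. Dividing macrophages were 3.77% of all cells in aged plaque replicate 4 (interval 3.16 to 4.48%), against 0 to 0.462%. Smooth muscle cells were 19.5% in young plaque replicate 1 (45 of 231 cells, interval 14.9 to 25.1%), against 6.45% to 8.27%. The median depth in aged plaque replicate 1 was 2000 UMIs per cell, against 5002.5 to 5332. In CD8 T cells of aged plaque replicate 4, Hbb-bs was at 7.03 normalized UMIs per 10000, against 0.470 to 1.03, and Rgs16 at 4.80, against 1.78 to 2.01.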

How the results depend on the processing

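The tests with edgeR and TMM, weights by cell number, TMM-scaled means, rows with agreeing names, the length trend, averaged replicates, and without the class named CD4 Complement, the natural killer T chain or aged plaque replicates 1 and 4 were chosen after the results were seen. Simulated recovery of 2-fold changes in genes of at least 10 counts was 54% in plaque CD8, 17% in plaque CD4 and 16% in spleen Gzmk effector memory T cells. Of 455 named gene results, 3741 of 4187 values without 1 library and 6793 of 7441 in other settings kept direction and threshold side. Another 433 and 605 were weaker, 5 and 27 stronger, 8 and 16 changed sign without passing (moved) and 0 reversed with a call. Of 80 list results 427 of 520 and 156 of 240 held. Another 34 and 70 were weaker, 30 and 6 stronger, 29 and 7 moved and 0 and 1 reversed. Class shares were left out, since no spleen class could pass and no plaque class did. Causes not given below were not tested.

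Without 1 library the counts of called genes ranged from 346 to 3080 in spleen CD8, 1521 to 3067 in spleen CD4, 0 to 29 in plaque CD8 and 16 to 35 in plaque CD4 T cells, from 10 to 33 and 2 to 124 for the difference of age effects in CD8 and CD4 T cells, and from 2252 to 3018 and 1303 to 2457 for plaque against spleen. In cell subclasses they ranged from 0 to 27 and 0 to 8 in Gzmk effector memory cells of spleen and plaque, 11 to 2835 in naive CD8, 140 to 1552 in central memory and 4 to 1681 in naive CD4 T cells. Classes without overlap ranged from 26 to 28 in spleen and 2 to 5 in plaque. Leaving out a library cannot make separate ages overlap, so these class counts could not fall and do not test the classes. Called lists ranged from 44 to 49 and the clonotype difference from 1.77 to 3.23 points. The Trbv evenness difference ranged from -0.661 to -0.204 in spleen and -1.66 to 0.347 in plaque.

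Count-based tests called more genes. Counts for spleen CD8, plaque CD8, plaque against spleen in CD8, and the difference of age effects in CD8 and CD4 T cells were 1483, 26, 4646, 269 and 166 with DESeq2, 1433, 14, 4462, 156 and 84 with edgeR and TMM, and 1595, 36, 4819, 160 and 100 with edgeR without filterByExpr. Without TMM the last 4 were 15, 4253, 129 and 80. Spleen CD4 T cells had 3416 calls with edgeR and TMM and 3749 without filterByExpr, which called 139 in plaque CD4 T cells. The median of all genes in spleen CD8 T cells was -0.10 with limma and 0.02 with DESeq2, and for plaque against spleen in CD4 T cells -0.21 and 0.01, where the split of 685 up and 1290 down turned to 1634 and 951. TMM-scaled means turned 1358 up and 859 down in spleen CD4 T cells to 1146 and 1668.

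Other settings moved counts as follows. No filter on low values left 9 genes in plaque CD4 and 0 in plaque CD8 T cells (limma, 700 at an unadjusted p under 0.05), and 57 and 8 for the difference of age effects in CD4 and CD8 T cells. A pseudocount of 0.01 gave 6 in plaque CD4 and 46 for the CD8 difference, and a pseudocount of 1 gave 24 and 10 for the CD4 and CD8 differences. Cells gated by their own transcripts left 2 genes in plaque CD4 and 2 in plaque CD8 T cells, and at least 50 cells per library, which drops young replicate 1, gave 29 in plaque CD8 T cells. Weights by cell number gave 664 for plaque against spleen in CD4 T cells, 5 for the CD8 difference and 0 for the CD4 difference (limma, 234 at an unadjusted p under 0.05). A joint model of all libraries pools the spread of both tissues and called 127 in spleen CD8, 136 in spleen CD4, 25 in plaque CD8 and 126 in plaque CD4 T cells. Removal of the length trend gave 38 for the CD8 difference. Averaging aged spleen replicates 1 and 2, which leaves fewer samples, gave 484 in spleen CD8 T cells and 3 for the CD4 difference. Without the class named CD4 Complement, 6 genes passed in plaque CD4 T cells and 5 for the CD4 difference. Without aged plaque replicates 1 and 4 (lowest depth over all cells, most cells), 10 genes passed in plaque CD8 T cells, 6 shared. Lists called fell from 47 to 3 with an estimated correlation and 24 with fry. The most used Trbv gene took a smaller share in aged spleen by -0.596 points, which runs against the lower evenness.

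The replicate number as a block gave 267 genes in spleen CD8, 1330 in spleen CD4, 24 in plaque CD8 and 25 in plaque CD4 T cells, 28 and 5 classes, 51 lists, an exact p of 0.25 for clonotypes, and a median of -0.459 for the naive list in plaque CD4 T cells in place of -0.03. Same-number libraries correlated by -0.308, -0.0457 and -0.385 in spleen CD8, -0.211, -0.0213 and -0.403 in spleen CD4, 0.00271, 0.0707, 0.0177 and 0.109 in plaque CD8, and -0.0146 and 0.0593 in plaque CD4 T cells, so the numbers do not pair the samples. No plaque cell had a named clonotype, so no alternative for plaque clonotypes was run. The inverse Simpson number of clonotypes was not run, since small clonotypes were not named. A minimum of 50 cells changed no spleen library of the CD8 and CD4 comparisons and left too few plaque libraries for CD4 T cells. It left no young spleen library for Gzmk effector memory cells (42, 24 and 23 cells), so that comparison had no such value.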

Other observations

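The gene tests within cell subclasses and of other splits were chosen after the results were seen, tests at equal class shares before.

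Gzmk effector memory CD8 T cells of the spleen numbered 23 to 42 per young library. Gzma (ENSMUSG00000023132, chromosome 13, 113093825 to 113100981), a granzyme, fell from 12.2 ± 0.951 to 0.828 ± 0.805 normalized UMIs per 10000 (SD, n = 3 each, log2 change -4.08 ± 0.45, limma adjusted p = 0.00920). Cx3cr1 (ENSMUSG00000052336, chromosome 9, 119901616 to 120069879), a chemokine receptor of terminal effector cells, fell from 2.00 ± 0.430 to 0.408 ± 0.0531 (-2.03 ± 0.25, adjusted p = 0.00932). S1pr5 (-2.24), an exit receptor, Zeb2 (-1.92 ± 0.24) and Klf2 (-1.25 ± 0.15), transcription factors, fell too. Lmo1, a transcription cofactor, had no UMIs in young cells and was at 0.812 ± 0.192 in aged cells. In all 10 of 7745 genes passed, 3 up and 7 down, with 920 at an unadjusted p under 0.05. There were 0 without aged replicate 2 or young replicate 1, 1 without aged replicate 1 or 3, 2 without young replicate 2 and 27 without young replicate 3. Gzma was lost without aged replicate 2 (adjusted p = 0.0542), young replicate 1 (0.122) or young replicate 2 (0.103). With both likest aged libraries averaged to 1 sample no gene passed (limma, 373 at an unadjusted p under 0.05), and edgeR with TMM called 72 genes. In the same class in plaque, Il7r, a survival receptor, rose from 1.35 ± 0.356 to 3.83 ± 1.13 (SD, n = 4 each, 1.42 ± 0.23, adjusted p = 0.016, and 0.191 without aged replicate 3), 1 of 2 genes called.

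Central memory CD8 T cells of the aged spleen carried more S100a6, from 2.06 ± 0.43 to 13.3 ± 1.67 normalized UMIs per 10000 (SD, n = 3 each, 2.65 ± 0.14, adjusted p = 1.12e-08). Fcgr2b (1.82 ± 0.18), an inhibitory Fc receptor, Gzmm (1.38 ± 0.11) and Id2 (1.21 ± 0.12) also rose, and Id3 (-1.63 ± 0.17), a regulator that opposes effector fate, fell. In all 516 of 7529 genes passed, 145 up and 371 down. There were 140 to 148 without aged replicate 1 or 2 or young replicate 1 or 2, 864 without young replicate 3 and 1552 without aged replicate 3. With edgeR and TMM the split turned to 401 up and 229 down. Naive CD8 T cells also changed. Ccl5 rose from 0.559 to 1.85 (1.56 ± 0.16, adjusted p = 0.000471), Slpi (1.37) and Bmpr1a (1.31) rose, and Rab4a (-1.15) fell. In all 465 of 7358 genes passed, 65 up and 400 down, or 322 up and 146 down with edgeR and TMM. That count was 27, 12 and 2835 without aged replicates 1 to 3, and 21 and 11 without young replicates 1 and 2. It was 84 after removal of the length trend, with 60 genes shared. In naive CD4 T cells 9 of 7548 genes passed, among them Bmpr1a (1.76 ± 0.17) and Pdlim4 (-1.08 ± 0.13), and 4 to 5 without aged replicate 1 or any 1 young library but 1681 without aged replicate 3.

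A shift between named classes could account for age differences in spleen T cells as a whole. At equal shares of 5 classes, called genes of CD8 T cells kept a median of 64.3% of their difference, falls 79.8% and rises 34.9%. Falls cannot decide on the shift, since a fall of all classes is kept too. The median of all genes was -0.168 in naive and -0.124 in central memory cells. Gzmk kept 7.54%, Ccl5 11.7%, Ctla2a 14.1% and S100a4 14.7%, so the shift stays open for most of their difference. Called genes of CD4 T cells kept a median of 49.3% within 7 classes, so a shift cannot be told from a change within classes. This left out Th1 cells, and Nkg7 rose by 1.12 in these classes, 2.03 in all. Of the called genes Foxp3 kept 15.3%, Izumo1r 15.4%, Tox 14.8% and Pdcd1 -10.4%, so the shift stays open for most of their difference.

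Other splits of the same libraries were refitted for each comparison. In plaque CD8 T cells the real split called 9 genes and the highest of 34 others 7 (1 in 35, the smallest possible). Without young replicate 3 the real split called 0, so chance was not excluded. It was excluded for plaque against spleen, with 2807 genes against at most 16 in CD8 and 1975 against 4 in CD4 T cells. In Gzmk effector memory cells of plaque 5 of 35 splits called at least the real 2 genes, the highest 3, so chance was not excluded. For 3 against 3 libraries the splits are too few for a share under 0.05. The real and highest other counts were 949 and 0 in spleen CD8, 2217 and 1 in spleen CD4 and 27 and 4 in plaque CD4 T cells. They were 10 and 0, 465 and 0, 516 and 3, and 9 and 0 in Gzmk effector memory, naive CD8, central memory and naive CD4 T cells of the spleen, each reached by 1 split.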
